A study of Solenopsis invicta with 32 samples.

How the data were processed

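RNA from brains and ovaries of 16 fire ant gynes was sequenced as 32 libraries, made from 1.6 ng of total RNA per brain and 8.0 ng per ovary per the labels' protocols. Per the labels, gynes were grouped by treatment (overwintered or spring-reared) and organ, with 8 libraries per group, and libraries of the same colony code were taken as the 2 organs of 1 gyne. The labels give 1 gyne per colony, so replicates are separate animals and colonies.

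The deposited gene counts are whole numbers per gene model made by the authors; Trim Galore 0.6.5, STAR 2.7.3a and edgeR are named in the submitters' processing notes, and the genome build and annotation are not given in the sources used here. The column of counts without regard to strand was used, since Smart-seq2 does not mark strand; reads of overlapping or antisense genes and of near-identical gene copies cannot be separated in it. The 4 lines that name no gene (unmapped, multimapping, no-feature and ambiguous reads) stayed out of library sizes and tests. Unmapped reads averaged 17.3% in overwintered and 17.2% in spring-reared brains and 3.47% and 3.55% in ovaries. The authors also deposited CPM tables of 7655 genes for brain and 8031 for ovary; all their values equal the gene counts divided by their sum over the listed genes, within a relative tolerance of 1e-06, so genes were left out by the authors before scaling. These CPM values were used only to take the authors' list of genes as an alternative filter.

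Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr by group, robust dispersions, quasi-likelihood F-test) for each organ apart and, for the interaction, in 1 model of 4 group means over all 32 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values in the text use the TMM-adjusted library sizes of each organ. Principal components used log2 CPM with a pseudocount of 2. Gene sets were tested with camera of limma 3.58.1 (preset correlation 0.01, and an estimated one beside it) and fry. Library measures were compared by exact two-sided permutation tests in scipy 1.17.1. All adjusted p-values for single genes are from edgeR's quasi-likelihood test unless another tool is named.

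The rule for named genes was, for each organ, the 6 higher and 6 lower genes with the largest absolute log2 fold change among those past the threshold with a mean of at least 5 CPM, and for the interaction the 3 genes with the lowest adjusted p in each direction. These tests and rules were fixed before the data were examined; choices made later are named as such. Since the files do not pair identifiers with names, the rest of the rule, which used 30 fixed gene lists, the 30 list tests, the cell type markers and the test of chromosome 16 could not be run, and only 4 identifiers are printed. Brain-enriched and ovary-enriched genes (1904 and 1196 of 10448, at least 4-fold, adjusted p under 0.05 in the contrast of organs over all libraries) and classes of mean CPM (limits 1, 10 and 100) were chosen after seeing the data. The other 7348 genes are written as genes of similar level in both organs. They only missed that cut, and similarity was not tested: some differed between organs by less than 4-fold with an adjusted p under 0.05. The redrawn organ classes used the contrast of organs in the libraries of 1 treatment.

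Alternatives were RLE size factors, DESeq2 1.42.0, limma voom with and without sample quality weights, quantile and cyclic loess normalization with limma voom, no filter and a stricter filter (1 CPM in 8 libraries), the replicate number or gyne as a block, 1 surrogate variable from sva 3.50.0, a threshold of 0.01, a log2 fold change of at least 1, the authors' listed genes, counts thinned to the smallest library (9612985), the 10 most abundant genes left out, and leaving out each library in turn or the libraries that stood apart.

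The 2 organs of a gyne deviated together from their group means: the correlation averaged 0.128 (permutation p = 1e-04, the smallest that 10000 pairings can give), and 12 of 16 brains correlated best with the ovary of their own gyne. The pairing comes from the colony codes in the labels. In no group did 2 libraries agree within sampling noise (chi-square per degree of freedom from 19.6 upwards for all 28 pairs of each group).

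The tests were tested on simulated data with 200 changed genes drawn from the real means, dispersions and library sizes. In the brain simulation of 9570 genes, edgeR recovered 14.9% of 1.5-fold, 52.2% of 2-fold and 87.9% of 4-fold changes with 3.74% false calls; in the ovary simulation of 9361 genes, 44.8%, 67.2% and 93.9% with 3.52%; and in the interaction simulation of 10448 genes, 14.9%, 44.8% and 71.2% with 4.4%. DESeq2 made 17.6% false calls in the brain and 14.1% in the ovary simulation. Changes of 1.5-fold were thus mostly missed in all 3 simulations. The interaction simulation gave each unchanged gene the same mean and dispersion in brain and ovary. Its rates therefore do not cover genes whose level or spread differs between organs.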

Results

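Young queens (gynes) of the fire ant Solenopsis invicta that had overwintered were compared with gynes reared in spring, in brain and in ovary, to look for genes tied to plasticity in queen weight. All gynes came from monogyne colonies, which hold a single egg-laying queen, and carried the SB/SB genotype of the social supergene. The 32 libraries formed 4 groups of 8, overwintered brain, overwintered ovary, spring-reared brain and spring-reared ovary. The 2 organs of each of the 16 gynes were sequenced, 1 gyne per colony, with Smart-seq2, a method for low amounts of RNA that amplifies polyadenylated transcripts and does not keep strand. Counts assigned to genes ranged from 9612985 to 23656547 per library, over 16314 gene models. The files do not pair the gene identifiers with names, and 0 of the 16314 identifiers matched the reference gene table. Genes are therefore described by organ, abundance and direction, and 4 are identified by the files' own identifiers.

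Overwintered and spring-reared brains separated along the first principal component, which held 18% of the variance. Ovaries separated along theirs, which held 28.1%, except spring-reared ovary 6, which lay at -9.15, next to the overwintered ovaries (-40.63 to -11.87), while the other 7 spring-reared ovaries lay between 24.63 and 39.17. Spring-reared brains 4 and 7 and overwintered ovary 1 stood apart from the rest of their groups along the second component. The colony codes of all overwintered gynes share one prefix and those of all spring-reared gynes another, and the labels do not say what the prefix marks, so whatever it marks cannot be told apart from treatment.

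**Figure D1:**
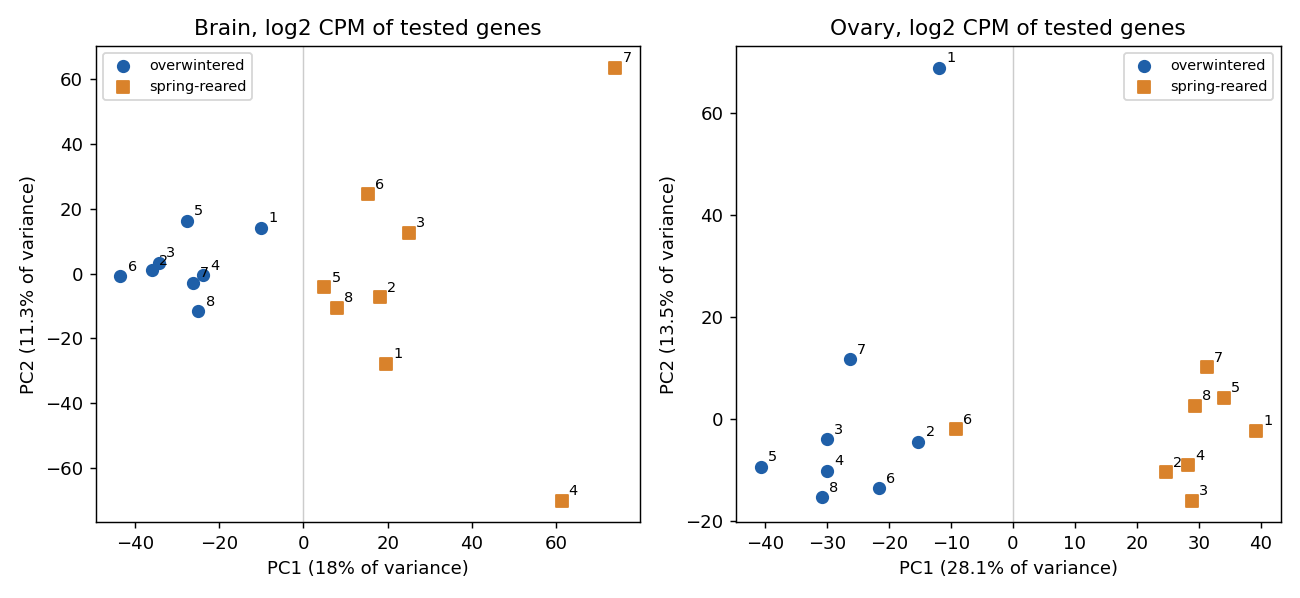
First and second principal components of log2 CPM for brain (left) and ovary (right) libraries, each point 1 library with its replicate number, circles overwintered and squares spring-reared. Spring-reared ovary 6 lies at -9.15 on the first component, and spring-reared brains 4 and 7 at 61.26 and 74.07.

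More genes were detected in overwintered than in spring-reared gynes in both organs. Overwintered brains held counts for 11006 ± 250.3 genes (SD, n = 8) and spring-reared brains for 10215 ± 240.1 (SD, n = 8; exact two-sided permutation p = 0.000155, the smallest possible for 8 against 8, adjusted p = 0.00186 over 12 library tests), and the ranges did not overlap. Overwintered ovaries held counts for 11318 ± 146.5 genes and spring-reared ovaries for 10962 ± 223.6 (n = 8 each; exact permutation p = 0.00124, adjusted p = 0.00746). In brain, 103 genes had counts in at least 6 overwintered and at most 1 spring-reared library, against 1 gene in the reverse direction. In ovary these numbers were 40 and 2. With counts thinned to equal depth they were 85 and 1 in brain and 28 and 4 in ovary. The mean difference in genes detected in ovary was 355.4, and 278.2 at equal depth (exact permutation p = 0.00342, n = 8 each). The other 10 tests, on total counts, unmapped, multimapping and no-feature reads and the share of the 10 most abundant genes, did not pass the correction, with the lowest adjusted p at 0.0731 (exact permutation tests, n = 8 each).

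**Figure D2:**
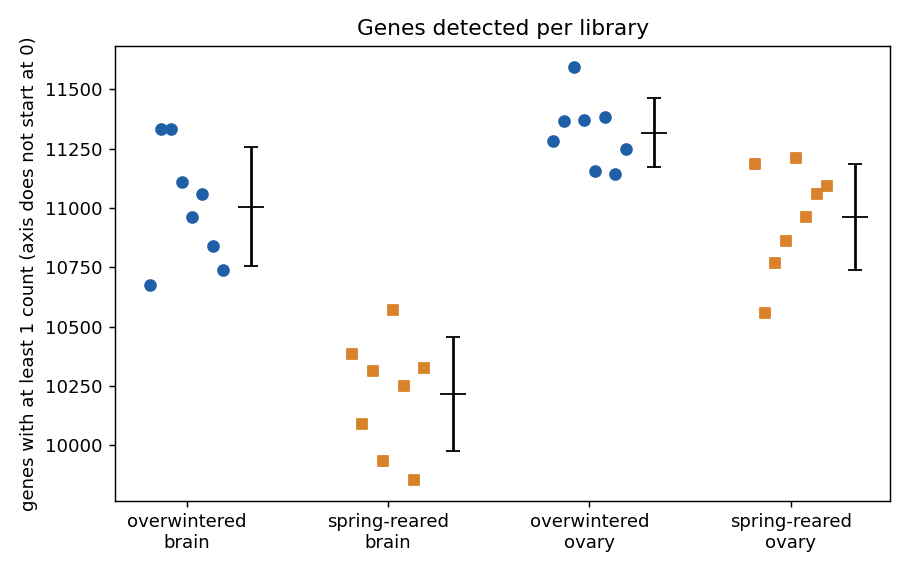
Genes with at least 1 count in each library, by group, with the mean and SD of 8 libraries in black; the vertical axis does not start at 0. All overwintered brains lie above all spring-reared brains, with means of 11006 and 10215.

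In brain, the comparison asked which genes differed between overwintered and spring-reared gynes, and most of those that did were lower after overwintering. Of 9570 genes tested, 154 rose and 363 fell in overwintered brains. The rises numbered 81 without overwintered brain 2, 82 without overwintered brain 3 and 96 without overwintered brain 6, and 327 with DESeq2, 282 with limma voom with quality weights and 261 without weights. Abundant genes held 223 of the 363 falls, but 118 of 283 with quantile and 126 of 281 with cyclic loess normalization. Of the 2214 genes with a mean of 100 CPM or more, 223 fell and 22 rose, whereas among the 2295 genes of 1 to 10 CPM, 16 fell and 32 rose. The median log2 fold change of the called genes was 0.88 for rises and -0.66 for falls.

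The largest fall among brain genes of at least 5 CPM was that of SINVBB1_05896. It stood at 606.1 ± 407.4 CPM in spring-reared brains and 9.44 ± 10.9 CPM in overwintered brains (SD, n = 8; log2 fold change -6.03, SE 0.86, edgeR adjusted p = 0.00137), and all 8 overwintered brains lay below the spring-reared median. In ovary the same gene averaged 235.5 ± 131.8 CPM in spring-reared and 73.2 ± 52.1 CPM in overwintered gynes (n = 8), which missed the threshold (edgeR adjusted p = 0.0558). SINVBB1_08088 showed the largest rise, from 1.70 ± 1.92 to 24.9 ± 18.9 CPM (SD, n = 8; log2 fold change 3.88, SE 0.94, edgeR adjusted p = 0.0244), and was higher than the spring-reared median in 8 of 8 overwintered brains. Its call was lost without overwintered brain 3 (edgeR adjusted p = 0.0521) and without spring-reared brains 4 and 7 (adjusted p = 0.0602), and with 1 surrogate variable (adjusted p = 0.0718), over a range of 0.00323 to 0.132 across 29 alternatives. The 4 versions of limma voom gave larger folds: the call was lost with quality weights (log2 fold change 5.03, limma adjusted p = 0.132), without weights (5.40, adjusted p = 0.0639) and with quantile normalization (4.55, adjusted p = 0.0524), and kept with cyclic loess normalization (5.04, adjusted p = 0.0398). The 6 genes with the largest rises had log2 fold changes from 1.87 to 3.88, with 1 or 2 of the 6 calls lost in 9 of 16 fits that left out 1 library, and the 6 with the largest falls from -6.03 to -2.52; without spring-reared brain 7, 1 of these 6 falls moved by over 1.5 times and the range was -5.90 to -2.15.

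Genes at least 4-fold higher in brain than in ovary, a grouping chosen after seeing the data, were over-represented on both sides of the brain comparison. Of 1893 such brain-enriched genes, 113 fell (5.97%, against 3.26% of other genes; Fisher's exact adjusted p = 7.23e-07) and 49 rose (2.59% against 1.37%; adjusted p = 9.86e-04), over 12 such tests that treat genes as independent. As a set they did not shift in either direction (camera adjusted p = 0.554). The 601 ovary-enriched genes tested in brain had a median log2 fold change of 0.12. They ranked higher in overwintered brains (camera adjusted p = 0.00218, and 0.00906 with an estimated correlation). The call was lost with the replicate number as a block (camera adjusted p = 0.105). Only 10 rose (1.664% against 1.606% of other genes) and 9 fell (1.498% against 3.947%, Fisher's exact adjusted p = 0.942 and 0.00212). Across all brain genes the median was 0.218 at 1 to 10 CPM, 0.042 at 10 to 100 and -0.087 from 100 CPM. The set was not compared with genes of similar abundance, so its rank cannot be told apart from this trend. Drawn from 1 treatment alone, each group is leaned by its own brains, which are also one side of the comparison: 17 of 625 ovary-enriched genes rose and 5 fell when drawn from spring-reared libraries, and 9 of 612 rose and 20 fell when drawn from overwintered ones, so no direction can be read from these counts. Brain-enriched genes were over-represented on both sides with either draw, at 46 rises and 126 falls of 1883 and at 60 and 108 of 1904 (Fisher's exact adjusted p at most 0.00419). The mean number of genes detected differed in the same libraries, 11006 in overwintered and 10215 in spring-reared brains.

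The brain count fell to 323 without overwintered brain 2 and to 301, with 106 rises and 195 falls, without spring-reared brains 4 and 7. With limma voom the share of falls was 59.9% in place of 70.2% and stayed at 59.5% with quantile and 59.9% with cyclic loess normalization, but among genes of 100 CPM or more these normalizations took falls and rises from 242 and 26 to 118 and 66 and to 126 and 63.

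In ovary, the same comparison called more genes, as many up as down. Ovaries varied less within groups (edgeR common biological coefficient of variation 0.306, against 0.461 in brain). In simulated data, 44.8% of 1.5-fold changes were recovered in ovary and 14.9% in brain. The median absolute log2 fold change of called genes was 0.58 in ovary and 0.71 in brain. The larger count therefore does not show a larger response in ovary. Of 9361 genes tested, 496 rose and 494 fell in overwintered ovaries (773 and 698 with limma voom with quality weights), and 144 rises and 98 falls were at least 2-fold. Ovary-enriched genes, at least 4-fold higher in ovary than in brain, were over-represented among the rises: 137 of 1180 rose (11.6%, against 4.39% of other genes; Fisher's exact adjusted p = 2.73e-19) and 59 fell (5.00% against 5.32%; adjusted p = 0.873). The other rises comprised 304 genes that met neither cut, written as of similar level in both organs, and 55 brain-enriched genes. A large rise in ovary itself moves a gene towards the ovary-enriched group. With the group redrawn from spring-reared libraries alone, 116 of 1200 rose (9.67% against 4.66%; Fisher's exact adjusted p = 1.16e-10 over 8 tests). As a set the ovary-enriched genes ranked higher in overwintered ovaries (camera adjusted p = 0.0065), a call lost with an estimated correlation (adjusted p = 0.126 with an estimated correlation). Genes of 100 CPM or more were balanced, with 159 rises and 146 falls.

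The 6 largest ovary rises among genes of at least 5 CPM had log2 fold changes from 4.93 to 9.63, and 1 of the 6 calls was lost in 13 of 16 fits that left out 1 library. Without spring-reared ovary 6, all 6 were larger by over 1.5 times, from 6.03 to 11.18, and without overwintered ovary 5, which moved 2 of them by as much, they ranged from 4.73 to 8.92. The first of them, SINVBB1_11164, averaged 276.8 ± 336.6 CPM in overwintered ovaries, from 11.19 to 1033, and 0.353 ± 0.564 CPM in spring-reared ovaries (SD, n = 8; log2 fold change 9.63, SE 1.2, edgeR adjusted p = 3.3e-04). Its 8 spring-reared libraries held 38 counts in all and 4 of them held 0, so the size of the fold depends on few counts. Its log2 fold change was 10.58 without spring-reared ovary 6 and 8.92 without overwintered ovary 5, and with limma voom without weights the call was lost (adjusted p from 0.0591 to 0.0687 in 3 of 31 alternatives). In brain it was near 0 in both groups, with 2 counts over the overwintered and 12 over the spring-reared libraries. The largest fall was that of SINVBB1_06471, from 31.4 ± 35.0 CPM in spring-reared to 2.44 ± 2.34 CPM in overwintered ovaries (SD, n = 8; log2 fold change -3.70, SE 0.81, edgeR adjusted p = 0.00917), below the spring-reared median in 8 of 8. Spring-reared ovary 5 held 112.4 CPM of it, and without that library the log2 fold change was -3.03 (edgeR adjusted p = 0.0152). The 6 largest falls had log2 fold changes from -3.70 to -2.29; 1 or 2 of the 6 calls were lost in 15 of 16 such fits, and without spring-reared ovary 5 the range was -3.03 to -2.02 with 2 calls lost. Without spring-reared ovary 6, which stood next to the overwintered ovaries, 993 genes were called, and 1059 without it and overwintered ovaries 1 and 5.

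**Figure D3:**
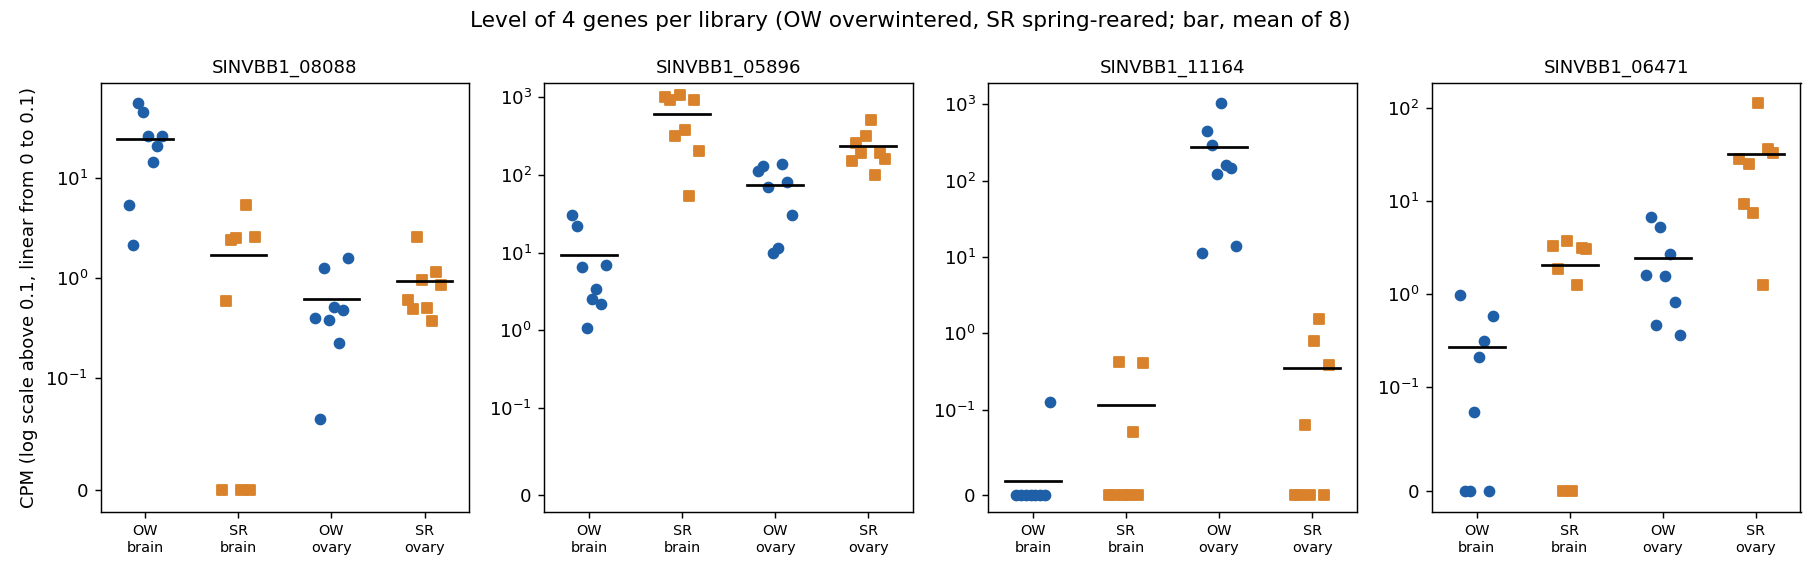
CPM of 4 genes in each library, by treatment and organ, on a vertical axis that is logarithmic above 0.1 and linear from 0 to 0.1; each point is 1 library and each bar the mean of 8. SINVBB1_11164 lies between 11.19 and 1033 CPM in overwintered ovaries and at most at 1.559 in spring-reared ovaries.

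Whether the treatment difference itself differed between organs was tested over all 32 libraries. The model took 1 dispersion per gene for both organs, although brain varied more (edgeR common biological coefficient of variation 0.461, against 0.306 in ovary). RNA kits and inputs also differed between organs. Of 10448 genes, 285 differed, 114 with a more positive overwintered-minus-spring-reared difference in brain and 171 in ovary. With limma voom without weights these numbers were 140 and 126, and with quantile normalization 88 and 107. Among the 285, 83 were called in brain alone, 105 in ovary alone, 13 in both with opposite signs, 2 in both with the same sign and 82 in neither; the interaction test favours opposite signs by construction. SINVBB1_05896 differed, with a more negative change in brain (interaction log2 -4.35, SE 0.91, edgeR adjusted p = 0.00706), and SINVBB1_08088 differed in the other direction (4.42, SE 1.10, adjusted p = 0.0228). The first call was lost with limma voom without weights (adjusted p = 0.066), also with quantile (0.0954) or cyclic loess normalization (0.0691), over a range of 2.92e-05 to 0.0954 across 44 alternatives. The second was kept under all 44 (adjusted p from 0.0016 to 0.0463), with a larger value with the gyne as a block (5.32) and with limma voom (5.29 to 6.18). Its ovary side rests on few counts. SINVBB1_08088 averaged 0.618 CPM in overwintered and 0.941 CPM in spring-reared ovaries, with 83 and 103 counts in all. It was filtered out of the test of ovary alone. The 3 genes with the lowest adjusted p in each direction had interaction log2 values from 1.68 to 4.21 and from -4.67 to -2.63. With the gyne as a block, which fits the design because both organs came from the same gynes, 123 genes were called, 107 of them among the 285, and without overwintered ovary 1 the count was 434.

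Genes that changed in both organs mostly changed in the same direction, and mostly fell. Among 8613 genes tested in both, 85 fell in both organs against 18.4 expected from lists drawn independently (Fisher's exact p = 3.92e-35, adjusted 7.83e-35 over 2 tests), and 15 rose in both against 6.46 expected (p = 0.00194). Independent lists leave out that both organs came from the same gynes and deviated together (mean correlation 0.128). A further 12 fell in brain and rose in ovary, and 1 did the reverse; the 12 became 24 with limma voom with quality weights, 20 with DESeq2, 7 with quantile normalization and 5 without the 5 libraries that stood apart. Those 5 libraries were spring-reared brains 4 and 7, overwintered ovaries 1 and 5 and spring-reared ovary 6. Overwintered ovary 5 was lowest on the first component (-40.63) but within its group on the second (-9.45). The ovary set was revised after the data were seen. Without those 5 libraries, 56 fell and 17 rose in both, and with DESeq2 and limma voom 24 to 41 rose in both. The 85 shared falls had median log2 fold changes of -0.73 in brain and -0.84 in ovary; 28 of them were brain-enriched, 0 ovary-enriched and 57 of similar level in both organs. Across genes, which are not independent replicates, the log2 fold changes of the 2 organs had Pearson r = 0.27 and Spearman rho = 0.282. Both organs came from the same gynes, so part of such a relation arises with no treatment effect.

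**Figure D4:**
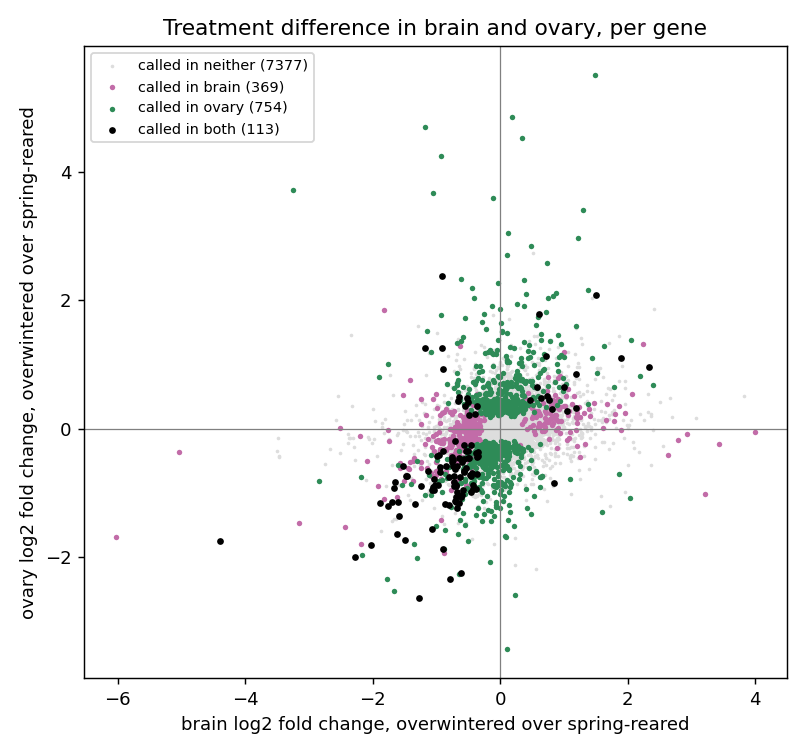
Log2 fold change, overwintered over spring-reared, in brain (horizontal) and ovary (vertical) for the 8613 genes tested in both organs, coloured by where each was called. The 113 genes called in both, in black, lie mostly in the lower left, where 85 fell in both organs.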

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

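The tests of explanations in this part were specified after the results they bear on had been seen. Regroupings of the gynes were planned for the correlation of fold changes between organs. How to read them, and their use for other measures, was specified after. Of 40 groups of 8 values examined for a value far from the others, 7 held one, where chance gives about 1 in 20, or 2. Overwintered ovary 3 held 23656547 gene counts, against 11444437 to 15779666 in the rest of its group. Overwintered ovary 1 had 8.97% no-feature reads, against 6.14% to 7.07%. In overwintered ovary 5 the 10 most abundant genes took 13.7% of counts, against 4.96% to 7.67%. SINVBB1_11164 reached 1033 CPM in overwintered ovary 5, against 11.19 to 438.5 in the others, and 0.129 CPM in overwintered brain 8, where the other 7 brains held 0. SINVBB1_06471 reached 112.4 CPM in spring-reared ovary 5, against at most 35.65, and SINVBB1_08088 reached 2.57 CPM in spring-reared ovary 3, against at most 1.16.

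The treatment difference differed between organs by the interaction test for 285 genes, among them SINVBB1_05896 (log2 -4.35), SINVBB1_08088 (4.42) and SINVBB1_11164 (-11.77); the last value rests on 2 and 12 counts in brain and depends on the prior count, so it is no measure of size. Its call was lost under 8 of 44 alternatives, among them those without overwintered brain 8 (edgeR adjusted p = 0.0558), spring-reared brain 3 (0.103) or spring-reared brain 8 (0.134), over a range of 1.03e-06 to 0.334.

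Chance is argued against as the source of the counts of called genes, within what the groupings can show. In 100 of the 6435 possible groupings of the 16 gynes, the real one included, 1 gave as many genes in brain (517, highest other 2), 1 in ovary (990, highest other 13) and 1 in the interaction (285, highest other 9). No share under 1 in 100 can be reached with this draw. The other groupings mix the treatments on both sides, which widens the spread within a side. Their counts are therefore not those of gynes without a treatment difference. The 100 genes changed alike in both organs were also reached by 1, the real one (highest other 0), but the other groupings called too few genes to share any, so this adds nothing to the counts. The correlation of fold changes between organs, the planned measure, was not set apart in this way: 7 of the 100 groupings gave r of 0.27 or more (highest other 0.306). The covariance of 0.0585, a measure not in the plan, was reached by 1, the real one (highest other 0.0332, mean of the others 0.0112). Covariance also rises with the size of the fold changes: the grouping with r of 0.306 had a covariance of 0.0309. Other groupings can hold part of the real treatment difference. The r values 0.306, 0.305 and 0.301 came from groupings that moved 4 of the 16 gynes to the other side, and 0.3 from 1 that moved 12. Those of 0.281 and 0.271 came from groupings that moved 10 and 6. Moving 12 equals moving 4 with the sides exchanged, and moving 10 equals moving 6, which leaves r unchanged. Others that moved 4 or 12 gave r as low as -0.004 and 0.053, so the part held does not alone set r. Groupings that moved 8 hold both treatments evenly on each side, and their r reached 0.209. That subset was picked after the values were seen. The planned comparison with all groupings thus leaves r not set apart.

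More genes were detected in all overwintered than in all spring-reared brains. Sequencing depth is argued against, since at equal depth the difference was 783.6 genes (exact permutation p = 0.000155, n = 8). Ovary RNA carried into the brain samples is argued against too: 73 abundant ovary genes that were low in spring-reared brains stood in overwintered brains at a median of 0.14% of their ovary level, whereas the 103 genes detected mainly there would need a median of 207.5%, and 60 of them were higher in brain than in ovary. A candidate explanation that stays open is that fewer molecules were captured in spring-reared brain libraries: their spread between libraries was 1.41 times that of overwintered brains for genes of 1 to 10 CPM (1.37 to 1.48 leaving out each library, 1.31 without spring-reared brains 4 and 7) and 1.01 times for genes of 100 CPM or more. A biological difference between treatments, and RNA of other head tissues, stay open untested.

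Spring-reared ovary 6 lay at 0.74 on an axis from the spring-reared mean (0) to the overwintered mean (1), built from genes called without it; the other spring-reared ovaries lay from -0.11 to 0.10 and overwintered ovaries from 0.58 to 1.13. A swap with an overwintered ovary of the study is argued against, since the lowest overwintered ovary lay at 0.58. A wrong treatment for the whole gyne is argued against, since its brain lay at 0.42 on the brain axis, below all overwintered brains (0.64 to 1.06), though above the other spring-reared brains (-0.06 to 0.38). Both printed brain genes also placed this brain nearest the overwintered ones. SINVBB1_05896 stood in it at 54.02 CPM, between the overwintered brains (up to 30.78) and the other spring-reared brains (202.5 upwards). SINVBB1_08088 stood at 5.439 CPM, the highest spring-reared value and above overwintered brains 1 (5.367) and 2 (2.18). A wrong label of this ovary alone remains possible at 0.74, and so does a gyne whose ovary had developed further, which no label records. SINVBB1_11164 stood in it at 1.559 CPM, below the lowest overwintered ovary (11.19), whereas the other 5 of the 6 largest ovary rises stood within the overwintered range.

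Genes that fell in both organs, 85 in all, outnumbered those expected from independent lists, a comparison that leaves out that the organs of a gyne deviate together. RNA carried over between organs is argued against as the whole cause, since 66 of the 85 would need a larger share carried over, in both directions, than the lowest 10% of abundant genes of the other organ allow (6.03% of the brain level in ovaries and 18.6% of the ovary level in brains, against medians needed of 22.5% and 65.4%). For the other 19 it stays open. These numbers depend on the limit: with a tighter limit of 0.789% and 8.05%, tried later, 81 of the 85 would need more. Whatever the prefix of the colony codes marks cannot be told apart from treatment, because 0 prefixes are shared by both treatments. The covariance of fold changes, a measure not in the plan, was 0.0585, and 0.0332 in the highest of the other groupings. Covariance also rises with the size of the fold changes. It thus does not decide whether deviations shared by the organs of a gyne are the whole source of their agreement. The planned correlation was not set apart from the other groupings, some of which hold part of the treatment difference. Such deviations stay open for the count of 85, since the other groupings called too few genes. RNA of another tissue in both organs stays open untested, as does overwintering itself, which was not tested apart from what the prefix marks.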

How the results depend on the processing

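Plain voom, quantile and cyclic loess normalization, the authors' listed genes, thinned counts, leaving out of the gene tests the 10 most abundant genes or the libraries that stood apart, and the tests of organ classes were chosen after seeing the data. The rest were fixed before. The cause of the shifts was not tested, except that stricter thresholds call fewer genes by construction. DESeq2 called 863 genes in brain, 526 in the interaction and 181 changed alike in both organs; voom with quality weights called 473 in the interaction. A threshold of 0.01 left 151 in brain, 342 in ovary, 85 in the interaction and 19 shared, and a log2 fold change of at least 1 left 138, 242, 163 and 15. Without spring-reared brains 4 and 7, 301 brain genes were called. Leaving out 1 library gave 323 (without overwintered brain 2) to 604 brain genes, 712 to 1177 ovary genes and 212 to 434 (without overwintered ovary 1) interaction genes. Replicate numbers name different colonies in the treatments and do not pair them (correlations of same numbers from -0.153 to 0.024 in brain and -0.207 to 0.136 in ovary); with the replicate number as a block 308 brain and 469 ovary genes were called, and with the gyne as a block, where organs are paired, 123 in the interaction. All other alternatives left the total counts within 1.5 times of those reported, although 20 of 238 counts by direction moved further. With the 10 most abundant genes left out of library totals, the totals still did not pass the correction (exact permutation adjusted p = 0.191 in brain and 0.559 in ovary). The 2 of 12 library tests past the threshold are on genes detected, a measure that this alternative does not touch. Of 728 comparisons for the 24 named genes, 635 kept the call, 93 lost it and 0 reversed; for the 9 interaction genes 380 of 396 kept it; for the 6 tests of organ classes 26 of 30 were unchanged, and the ovary-enriched set lost its call in brain with the replicate block (adjusted p = 0.105) and in ovary with an estimated correlation (adjusted p = 0.126), while genes of similar level in both organs gained a call with an estimated correlation in brain (adjusted p = 0.169 to 0.00906) and in ovary (0.102 to 0.00735). Of the 24 named genes, 11 kept their call throughout. SINVBB1_05896 kept its call under all 29 alternatives (log2 fold change -6.61 to -5.67), SINVBB1_08088 lost it under 6 of 29 (adjusted p 0.00323 to 0.132), SINVBB1_11164 under 3 of 31, all voom without weights (up to 0.0687), and SINVBB1_06471 under 1 of 31, the replicate block (up to 0.125). The gene list and chromosome 16 alternatives were not run, because identifiers could not be matched. Depth and spread limit low genes: in spring-reared brains the median CV was 0.686 at 1 to 10 CPM and 0.166 at 100 CPM or more.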

Other observations

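The authors' listed genes leave out 34 genes called in brain (23 higher and 11 lower in overwintered gynes) and 135 called in ovary (88 higher and 47 lower), of which 34 and 124 changed at least 2-fold. Genes whose 16 libraries did not overlap between treatments numbered 101 of 9570 tested in brain (1.05%) and 176 of 9361 in ovary (1.88%), where chance gives 0.0155%; 93 and 175 of them were called.

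Genes at least 4-fold higher in brain than in ovary were measured in ovary too, with no shift as a set (camera adjusted p = 0.918). Of 1059 tested there, 72 fell in overwintered gynes (6.80% against 5.08% of other genes, Fisher's exact adjusted p = 0.0351) and 55 rose (5.19% against 5.31%, adjusted p = 0.942). Redrawn from spring-reared libraries, 69 of 1074 fell and 64 rose (Fisher's exact adjusted p = 0.1085 and 0.355). From overwintered libraries, 82 of 1077 fell and 41 rose (adjusted p = 9.73e-04 and 0.0327). The result for falls thus depends on the draw. In the interaction, 71 of 1904 brain-enriched, 63 of 1196 ovary-enriched and 151 of 7348 genes of similar level were called. Of the brain falls tested in ovary, 71.5% had a negative log2 fold change there, with a median of -0.22, and of the brain rises 80.7% had a positive one, with a median of 0.23; since both organs came from the same gynes, part of this arises with no treatment effect.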
